A study of Mus musculus with 10 samples.

How the data were processed

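Liver RNA of male C57BL/6 mice with a liver-specific Pparg knockout was measured, per the labels, with libraries made from total RNA with an Illumina TruSeq kit and sequenced on a HiSeq instrument. The libraries fall into 2 groups of 5 by their treatment label, 0.5% CMC and DEHP at 2500 mg/kg body weight. The replicate numbers name the samples, and the main test does not treat them as pairs. The deposited table gives 1 FPKM value per gene and library, which per the file headers is the unit, that is fragments scaled by transcript length and by all mapped fragments. Genes carry NCBI gene IDs, and transcripts carry RefSeq identifiers or others outside RefSeq. Cuffdiff and the builds mm10 and GRCm38 are named in the submitters' processing notes with no version or role, and the aligner is not given in the sources used here. Because FPKM is relative to the library total, a fall of very abundant transcripts raises every other value, and because reads are assigned to genes upstream, copies that are nearly identical can trade reads. The table holds no raw counts, so no count model was used.

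Of 16874 rows, 16833 gene IDs matched a reference gene table of GRCm38.p6, from which coordinates were taken, and 22 symbols stored as dates were restored by gene ID. A total of 630 rows were at 0 in every library. Genes with at least 0.5 FPKM in at least 5 of the 10 libraries were tested, 11242 in all, as log2(FPKM + 0.5). A fold change is on that scale, which understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 with an intensity trend and robust variance, DEHP minus CMC, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. Levels are means ± SD over 5 libraries. Comparisons of library summaries used two-sided exact permutation tests over 252 regroupings, whose smallest p is 0.00794. Of the 57 lists fixed, 50 had enough tested members, and the list of mitochondrially encoded genes was not analysed here.

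The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named are 26 sentinel genes, the 12 highest and 12 lowest log2 fold changes among called genes with no overlap and a mean of at least 1 FPKM, the 10 smallest p, up to 6 members per list by smallest p, and the 5 most abundant genes per group. Some genes that this rule takes are not reported here. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, median-of-ratios scaling, quantile normalization, removal of the 10 most abundant genes, limma without trend or robust variance, array weights, the replicate number as a block, an exact permutation test per gene, a test against a fold of 1.5, and leaving out each library. A covariate from the first principal component of the 18 tested circadian clock genes, and leaving out CMC library 2 with DEHP library 5, were added after seeing the data. The split counts for each gene list were also added after the data were seen. For these, 100 of the 126 splits of the 10 libraries into 5 and 5 were drawn, the real one included.

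Total depth is unknown from FPKM values. Relative depth was estimated from 7820 single-transcript rows, where the ratio of a pair of libraries peaks at equal fragment numbers. On simulated libraries whose depths lie a few percent apart its largest error was 3.05%. That error is as large as the largest departure from equal depth simulated there. The simulation thus did not show that differences of a few percent are recovered. On depths far apart the estimate failed, with errors up to 32% and a disagreement between pairs of at least 0.125. The real libraries disagreed by 0.0024. In simulated data with 200 of 11242 genes changed in the comparison of DEHP with CMC, limma recovered 87.3% of changes of 1 and 97.3% of changes of 2 on the log2 scale, with 5.42% of calls false. Genes were drawn there independently from normal distributions, unlike real genes, so 5.42% is not the false share of the real calls. In the table of log2 correlations, r was 0.976 to 0.986 within CMC, 0.980 to 0.986 within DEHP and 0.964 to 0.978 between the groups, and at most 0.943% of tested genes had identical values in a pair of libraries, so no library was counted as a copy. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15, with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.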

Results

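Liver RNA was sequenced in 10 libraries from male C57BL/6 mice with a liver-specific knockout of Pparg, the gene of the lipid-regulating nuclear receptor PPAR gamma. Of these, 5 came from mice gavaged with 0.5% CMC, the vehicle, and 5 from mice gavaged with DEHP, a phthalate plasticizer, at 2500 mg/kg body weight. The labels give 12 mice per group of 20 to 30 g, and 5 libraries per group were analysed here. Each library is listed as a separate sample but no label names its mouse, so p-values measure the spread between these samples. The length of treatment is not given in the sources used here. The table held FPKM values for 16874 genes, of which 11242 passed the filter on low values. FPKM summed to 714302 ± 10866 per CMC library and 714452 ± 24455 per DEHP library (SD, n = 5 each, exact permutation p = 0.992, two-sided). Total depth is unknown. An estimate from the steps of low values put the relative depth of the 10 libraries between 0.98 and 1.028 of their mean. Simulations did not show that this estimate recovers such small differences. The comparison asks which liver transcripts differ after DEHP where hepatic Pparg is targeted. No library without the knockout was analysed here, so no part of a difference can be assigned to the knockout.

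Pparg was read in every library and was higher after DEHP. Its level was 2.4, 4.56, 4.14, 2.72 and 5.9 FPKM in CMC libraries 1 to 5 and 7.81, 5.5, 9.4, 7.79 and 7.04 FPKM in DEHP libraries 1 to 5. The mean rose from 3.94 ± 1.43 to 7.51 ± 1.41 FPKM (SD, n = 5 each), with a log2 fold change 0.89, SE 0.21, adjusted p = 0.0118. A two-sided exact permutation test gave p = 0.0159 for Pparg, and 0.0317 after adjustment over the sentinel genes. Adjusted over all tested genes, that test passed neither Pparg nor any other gene, and its smallest adjusted p was 0.0742. Pparg lies on chromosome 6 from 115360879 to 115490404 in GRCm38. The table has 1 value per gene over all its exons, and the labels do not name the deleted part, so this level checks nothing about the deletion. With the circadian component as a covariate, an alternative added after seeing the data, its adjusted p was 0.0813. Of the related receptors, Ppara had a log2 fold change of 0.20 (SE 0.08, adjusted p = 0.109) and Ppard of -0.44 (SE 0.22, adjusted p = 0.225), neither past the threshold.

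After DEHP, genes of mitochondrial fatty acid oxidation and of fatty acid uptake were higher, with 18 of 22 and 10 of 15 tested members. Genes of complement and coagulation were lower, with 23 of 37. The peroxisomal list had 20 of 33 members higher, cholesterol synthesis 18 of 26 and the proteasome 21 of 31. These last lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.0576, 0.193 and 0.115). In total 1025 genes were higher and 270 lower in DEHP than in CMC livers, by limma at an adjusted p below 0.05. Of these, 140 were higher and 42 lower by at least 1 on the log2 scale. The 5 values of each group did not overlap for 1203 tested genes, or 10.7% of those tested, where chance gives 0.794%. Higher calls made up 79.2% of all calls. The 50 most abundant genes took a share of summed FPKM of 46.9% ± 1.69 in CMC and 42.1% ± 2.22 in DEHP libraries (SD, n = 5 each, exact permutation p = 0.0159, adjusted p = 0.0794 over 10 library summaries), and Alb alone 4.65% ± 0.643 in CMC and 2.99% ± 0.327 in DEHP libraries (exact permutation p = 0.00794, adjusted p = 0.0794). The median-of-ratios size factor was 0.982 ± 0.0278 in CMC and 1.035 ± 0.0395 in DEHP libraries (exact permutation p = 0.0556, adjusted p = 0.185). With median-of-ratios scaling the split was 639 higher and 445 lower, and with quantile normalization 611 higher and 546 lower. With the circadian component as a covariate 540 genes were higher and 148 lower, and 48.6% of the calls above were among them. That component averaged -1.77 ± 3.10 in CMC and 1.77 ± 2.08 in DEHP libraries (SD, n = 5 each, exact permutation p = 0.0794, two-sided), so as a covariate it can also take up part of the difference between the groups. Without CMC library 2 and DEHP library 5, which stood apart on principal components 2 and 3, 948 were higher and 244 lower.

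**Figure D1:**
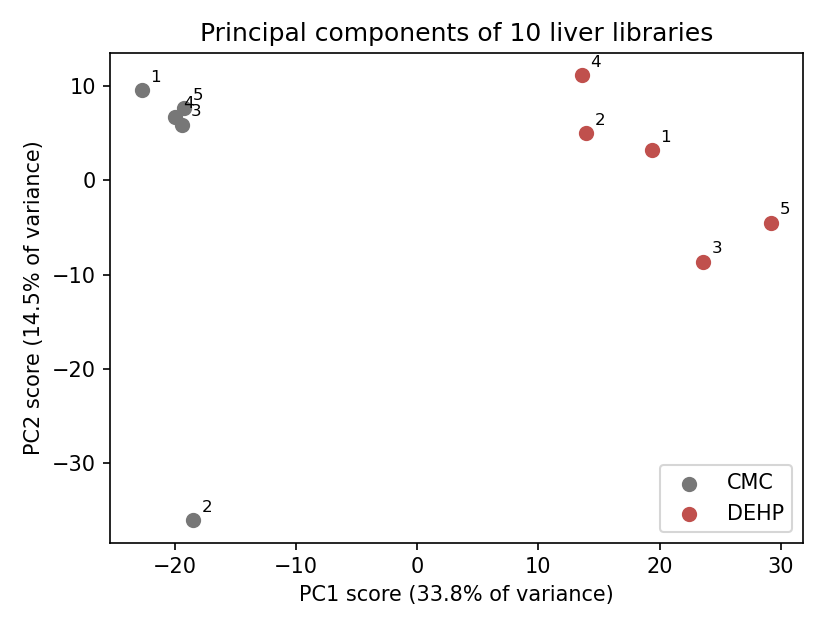
Scores of the 10 libraries on the first and second principal components of log2(FPKM + 0.5), with CMC in grey, DEHP in red and the replicate number beside each point. The 5 CMC libraries lie below −18 on the first component and the 5 DEHP libraries above 13, and CMC library 2 lies at −36.04 on the second.

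Among the 12 genes with the highest fold were Cyp4a14 and Cyp4a10, which oxidize fatty acids at their omega end. Cyp4a14 rose from 88.7 ± 84.9 to 2447 ± 454 FPKM (log2 fold change 5.27, SE 0.62, adjusted p = 0.00122) and Cyp4a10 from 114 ± 47.0 to 2396 ± 438 FPKM (log2 fold change 4.51, SE 0.38, adjusted p = 0.000143). Cyp2b9, a cytochrome P450, rose from 0.152 ± 0.143 to 27.7 ± 20.5 FPKM, and Mogat1, which makes diacylglycerol, from 0.0980 ± 0.104 to 14.2 ± 3.57 FPKM. The other genes of this set were Ehhadh, Rad51b, Cyp4a31, Vnn1, Cd36, Krt23, Ly6d and Cox6b2, with log2 fold changes of 4.21, 3.87, 3.78, 3.63, 3.39, 3.38, 3.30 and 3.27. Among the 12 genes with the lowest fold, Serpina1e, a secreted protease inhibitor of a family of near-identical copies, fell from 11149.8 ± 1340.0 to 1339 ± 953 FPKM (log2 fold change -3.32, SE 0.43, adjusted p = 0.00161). Gstp1, a glutathione transferase that also has a close copy, fell from 5437 ± 430.0 to 1769.8 ± 372 FPKM (log2 fold change -1.64, SE 0.12, adjusted p = 2.52e-06). Enho, Slc22a28, Apoa4, Cyp39a1, Sdr9c7, Ces1b and Mmd2 fell by log2 fold changes of -1.93, -1.87, -1.81, -1.74, -1.63, -1.46 and -2.42. Tff3 (-3.16), Meg3 (-2.15) and Slco1a1 (-1.58) completed the set, and each lost its call when a single library was left out. For Tff3 this held without CMC library 1, 4 or 5, or DEHP library 1, 2 or 5 (adjusted p = 0.0556 to 0.0920), for Meg3 without CMC library 3, 4 or 5, or DEHP library 1, 3 or 5 (adjusted p = 0.0557 to 0.0746), and for Slco1a1 without CMC library 1, 2, 3, 4 or 5, or DEHP library 1 or 3 (adjusted p = 0.0515 to 0.102).

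**Figure D2:**
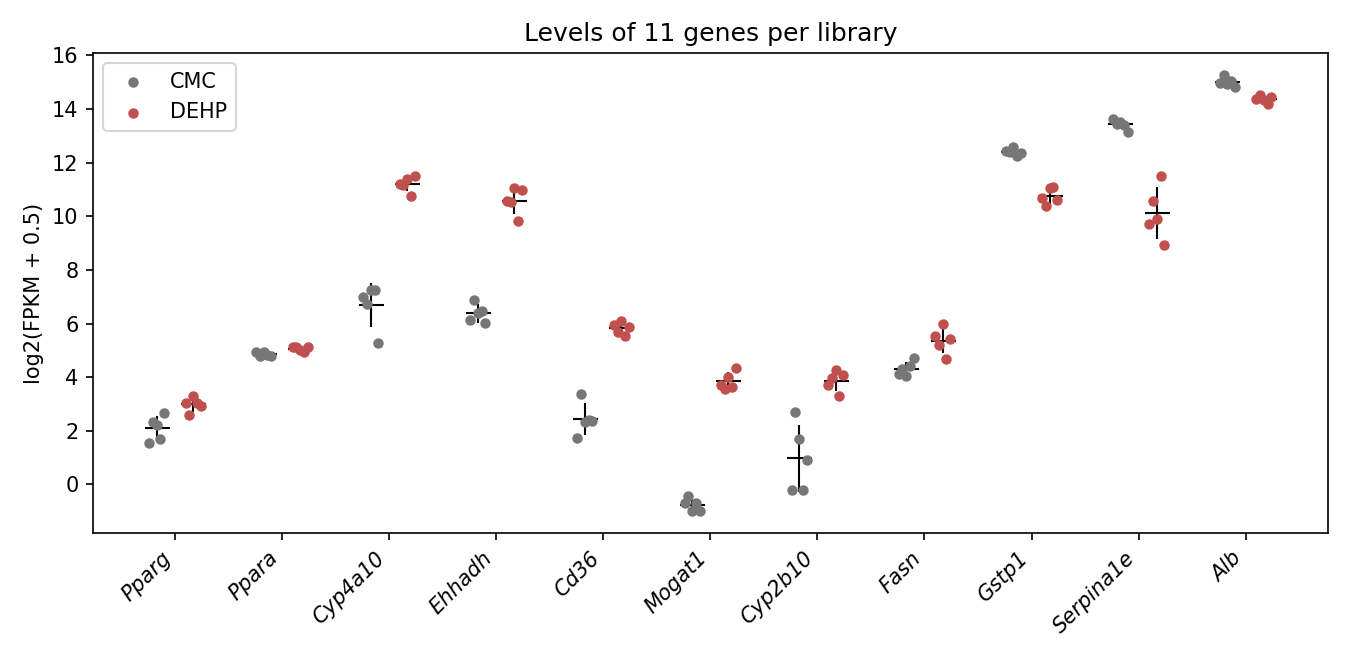
Levels of 11 genes in each library as log2(FPKM + 0.5), with 1 point per library, CMC in grey and DEHP in red, and the mean and SD of each group of 5 as black marks. Mogat1, Cd36, Ehhadh and Cyp4a10 lie higher in every DEHP library than in any CMC library, and Alb, Gstp1 and Serpina1e lie lower.

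Most tested members of each of 4 fatty acid oxidation lists were higher, and the mitochondrial list was the one that passed with an estimated correlation. Of the peroxisomal list, 20 of 33 tested members were higher and 0 lower, with 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.87e-15, adjusted p = 0.0576 with an estimated correlation, 1 of 100 splits). Ehhadh rose from 84.5 ± 20.9 to 1606 ± 497 FPKM and the thiolase gene Acaa1b from 541 ± 73.6 to 3940.3 ± 959 FPKM. Of the mitochondrial list, 18 of 22 were higher and 0 lower, with 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.64e-19, adjusted p = 0.0343 with an estimated correlation, 1 of 100 splits). Ucp2, an inner membrane carrier, rose from 16.9 ± 1.35 to 100.5 ± 22.8 FPKM. Decr1 rose from 63.7 ± 2.38 to 135 ± 8.11 FPKM and Acadm, a medium-chain acyl-CoA dehydrogenase, from 142 ± 15.2 to 294 ± 27.4 FPKM. Cpt1b had a log2 fold change of 1.24 (SE 0.57, adjusted p = 0.205) and was past the threshold only without DEHP library 2 (adjusted p = 0.0149). Of the omega oxidation list, 7 of 13 were higher and 1 lower, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000136, adjusted p = 0.1002 with an estimated correlation, 1 of 100 splits). The lower member was Cyp4f14, at 164 to 99.9 FPKM, while Aldh3a2 rose from 57.5 ± 7.44 to 205 ± 33.1 FPKM. Of the acyl-CoA thioesterases, 6 of 10 were higher and 0 lower, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.01e-05, adjusted p = 0.115 with an estimated correlation, 1 of 100 splits). Acot1 rose from 30.6 ± 12.6 to 151 ± 68.7 FPKM.

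The list of PPAR alpha signature genes, which shares members with these lists, had 22 of 35 tested members higher and 1 lower, with 25 higher and 4 lower adjusted over the list alone (camera adjusted p = 2.80e-15, adjusted p = 0.111 with an estimated correlation, 1 of 100 splits). Retsat, a retinol saturase, rose from 166 ± 32.1 to 939 ± 146 FPKM and Vnn1, a pantetheinase, from 4.04 ± 3.26 to 48.3 ± 9.90 FPKM. Several genes often grouped with fasting were not past the threshold, with Pdk4 at 0.34 (SE 0.41, adjusted p = 0.660) and Fgf21 at -1.18 (SE 0.62, adjusted p = 0.271) on the log2 scale. Of the ketogenesis list, 4 of 6 were higher and 1 lower, with 4 higher and 2 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0631, adjusted p = 0.440 with an estimated correlation, 8 of 100 splits). Without CMC library 1 or 3 its camera adjusted p was 0.0293 and 0.0467.

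Genes of fatty acid uptake were also higher. Of the uptake list, 10 of 15 were higher and 0 lower, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.09e-10, adjusted p = 0.0343 with an estimated correlation, 1 of 100 splits). Cd36, a fatty acid receptor, rose from 5.31 ± 2.64 to 56.8 ± 8.45 FPKM and Slc27a1, a fatty acid transporter, from 2.05 ± 0.443 to 20.9 ± 4.77 FPKM. Lpl, the lipoprotein lipase, rose from 3.94 ± 1.69 to 35.2 ± 6.90 FPKM and Fabp1, the liver fatty acid binding protein, from 6556 ± 1139 to 14359 ± 1595 FPKM. Of the list of PPAR gamma lipid storage genes, 7 of 16 were higher and 1 lower, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.16e-06, adjusted p = 0.0576 with an estimated correlation, 1 of 100 splits). Its higher members included Mogat1, Cd36, Lpl, Pparg itself and Fitm1, which rose from 10.8 ± 4.67 to 68.8 ± 11.6 FPKM. The lower member was Plin4, a lipid droplet coat protein, which fell from 3.59 ± 1.89 to 0.982 ± 0.617 FPKM and had an adjusted p of 0.111 with the circadian component as a covariate. Fabp4 at 0.36 (SE 0.46, adjusted p = 0.687) and Cidec at 0.71 (SE 0.25, adjusted p = 0.0883) were not past the threshold, but Cidec was without DEHP library 2 (adjusted p = 0.0311). Cidea was too low to be tested. Of the lipid droplet proteins 5 of 17 were higher and 2 lower, with 8 higher and 3 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.141, adjusted p = 0.518 with an estimated correlation, 26 of 100 splits). Hsd17b11, a dehydrogenase of lipid droplets, rose from 96.0 ± 7.78 to 529 ± 68.4 FPKM. Of the triglyceride synthesis list, 4 of 14 were higher and 0 lower, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.159 with an estimated correlation, 2 of 100 splits). Gpat3 rose from 1.18 ± 0.524 to 3.57 ± 0.870 FPKM.

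Of the cholesterol synthesis genes, 18 of 26 were higher and 0 lower, with 23 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.68e-12, adjusted p = 0.193 with an estimated correlation, 5 of 100 splits). Acat2, which makes acetoacetyl-CoA, rose from 40.8 ± 6.65 to 101 ± 34.1 FPKM. Of the lipogenesis list 9 of 26 were higher and 1 lower, with 16 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00784, adjusted p = 0.518 with an estimated correlation, 18 of 100 splits). Me1, the malic enzyme, rose from 48.0 ± 2.67 to 142 ± 57.4 FPKM and Fasn, the fatty acid synthase, from 19.7 ± 3.76 to 42.5 ± 13.5 FPKM. Pklr, the liver pyruvate kinase, fell from 49.1 ± 13.6 to 24.3 ± 4.59 FPKM. With the circadian component as a covariate Fasn had an adjusted p of 0.0673. Scd1 at 1.10 (SE 0.38, adjusted p = 0.102) and Srebf1 at 0.37 (SE 0.16, adjusted p = 0.157) were not past the threshold, although Scd1 was without DEHP library 2 (adjusted p = 0.0410). The lipoprotein list went both ways, with 7 of 29 higher and 5 lower, 10 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.878). Pltp, a phospholipid transfer protein, rose from 18.1 ± 1.90 to 174 ± 73.6 FPKM and Apoa4 fell from 101 ± 30.6 to 27.7 ± 4.43 FPKM. Bile acid genes also went both ways, with 5 of 26 higher and 4 lower, 8 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.878). Cyp8b1, which sets cholic acid output, rose from 238 ± 42.5 to 406 ± 69.6 FPKM, and Cyp39a1, an oxysterol hydroxylase, fell from 9.92 ± 2.84 to 2.59 ± 0.581 FPKM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 1.24 (SE 0.57, adjusted p = 0.219).

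Some xenobiotic genes were higher. Of the CAR and PXR targets 10 of 28 were higher and 0 lower, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000186, adjusted p = 0.160 with an estimated correlation, 2 of 100 splits). Cyp2b10, a marker target of CAR, rose from 2.17 ± 2.34 to 14.6 ± 3.69 FPKM and the export pump gene Abcc3 from 30.4 ± 4.05 to 67.3 ± 3.59 FPKM. Cyp3a11, a marker target of PXR, was at -0.22 (SE 0.16, adjusted p = 0.429) and not past the threshold. Of the NRF2 targets 12 of 28 were higher and 0 lower, with 13 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000914, adjusted p = 0.518 with an estimated correlation, 20 of 100 splits). Gstm4 rose from 41.6 ± 3.36 to 95.2 ± 25.4 FPKM and Nqo1, a quinone reductase, from 3.18 ± 1.40 to 7.07 ± 1.17 FPKM, where Nqo1 had an adjusted p of 0.0967 with the circadian component. Among AHR targets 1 of 5 was higher, Nqo1 again, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.884). The other conjugation enzymes had 9 of 26 higher and 4 lower, 10 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.687), with Gstt2 rising from 52.5 ± 9.55 to 142 ± 33.8 FPKM.

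Genes of complement and coagulation fell. Of the complement and coagulation genes 23 of 37 were lower and 0 higher, with 0 higher and 27 lower adjusted over the list alone (camera adjusted p = 4.26e-22, adjusted p = 0.0343 with an estimated correlation, 1 of 100 splits). C6, C8a and C9, parts of the membrane attack complex, fell from 95.5 ± 10.6 to 38.7 ± 12.0 FPKM, from 199.8 ± 19.0 to 102 ± 18.4 FPKM and from 284 ± 43.4 to 131 ± 32.3 FPKM. Of the hepatocyte identity genes 9 of 23 were lower and 1 higher, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 3.40e-07, adjusted p = 0.0576 with an estimated correlation, 2 of 100 splits). Alb, the most abundant transcript in CMC livers, fell from 33190.3 ± 4054 to 21276 ± 1793 FPKM (log2 fold change -0.64, SE 0.09, adjusted p = 0.000445). Of the acute phase list 6 of 29 were lower and 1 higher, with 3 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0334, adjusted p = 0.625 with an estimated correlation, 42 of 100 splits). Its median log2 fold change was −0.06 and its mean 0.18, so that these differ in sign, and the fibrinogen genes Fga, Fgb and Fgg fell from 1729 to 1349 FPKM, 2863 to 2186 FPKM and 2598 to 1891 FPKM. The acute phase call was lost when any 1 of 6 libraries was left out, CMC 1 and 5 and DEHP 1, 2, 3 and 4, with adjusted p of 0.0605, 0.435, 0.0577, 0.0763, 0.0739 and 0.0658. Of the periportal genes 3 of 19 were lower and 0 higher, with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 1.75e-05, adjusted p = 0.268 with an estimated correlation, 6 of 100 splits). Of the pericentral genes 2 of 22 were higher and 1 lower, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.374). Among the most abundant transcripts Apoe and Apoa2 had log2 fold changes of 0.27 (SE 0.08, adjusted p = 0.0396) and 0.33 (SE 0.08, adjusted p = 0.0147), and neither call held with median-of-ratios scaling. Apoe also lost its call without CMC library 1, 3, 4 or 5, or DEHP library 1 or 3 (adjusted p = 0.0571 to 0.0962).

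**Figure D3:**
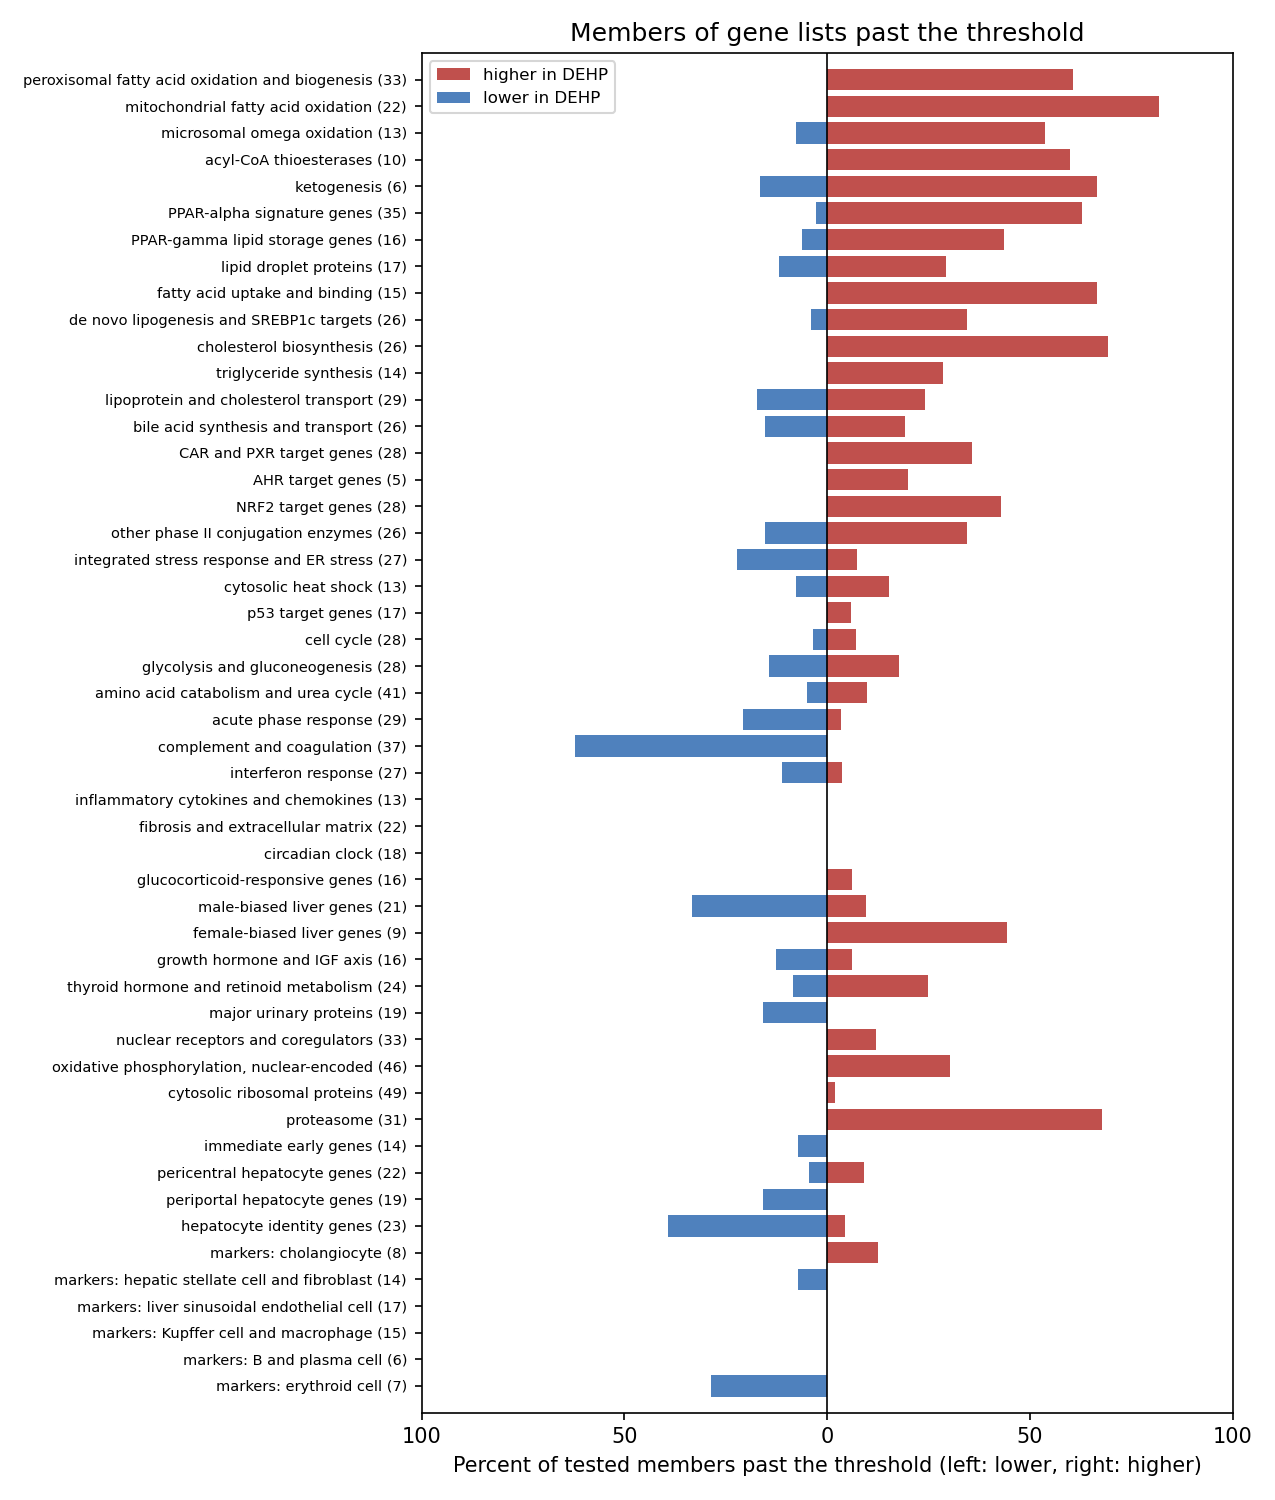
Percent of the tested members of each gene list that were higher (red, right) or lower (blue, left) in DEHP at an adjusted p below 0.05 over all genes, with the number of tested members in brackets. The mitochondrial fatty acid oxidation list has 18 of 22 members higher, and the complement and coagulation list has 23 of 37 lower.

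Neither the male-biased nor the female-biased list of liver genes passed with an estimated correlation, and a difference between these lists was not tested. Of the male-biased list 7 of 21 tested members were lower and 2 higher, with 2 higher and 7 lower adjusted over the list alone (camera adjusted p = 2.99e-05, adjusted p = 0.455 with an estimated correlation, 25 of 100 splits). The higher members were Cyp4a12a and Cyp4a12b, from 141 ± 55.7 to 369 ± 14.4 FPKM and from 46.5 ± 15.4 to 187 ± 12.5 FPKM, and Serpina1e was among the lower, as were C6 and C8b, which also belong to the complement list. Of the female-biased list 4 of 9 were higher and 0 lower, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.41e-06, adjusted p = 0.125 with an estimated correlation, 2 of 100 splits), among them Cyp2b9 and, shared with the omega oxidation and PPAR alpha lists, Cyp4a10 and Cyp4a14. Of the major urinary protein genes 3 of 19 were lower and 0 higher, with 0 higher and 3 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.136, adjusted p = 0.867 with an estimated correlation, 67 of 100 splits). Its median was −0.09 and its mean 0.04, which differ in sign. Mup3 fell from 9574 ± 2514 to 3422 ± 1356 FPKM, with an adjusted p of 0.0781 under the circadian covariate, while Mup7 at -0.73 (SE 1.52, adjusted p = 0.826) and Mup11 at 0.02 (SE 0.40, adjusted p = 0.987) were not past the threshold. These near-identical copies can share reads, so single Mup and Serpina1 values are uncertain. CMC library 2 stood apart here, with 184 FPKM of Mup7 against a group mean of 18971. Without it Mup7 had a log2 fold change of -2.13 in limma (adjusted p = 0.113), the lowest over the alternatives run, and without CMC library 1 it had -0.29, the highest. Neither was past the threshold. At the preset correlation the Mup list had a camera adjusted p of 2.67e-05 without CMC library 2. Without DEHP library 4 that p was 0.00684. The estimated correlation of this list was 0.711 over all 10 libraries, and leaving out a library was not tested with it. Of the growth hormone and IGF genes 1 of 16 was higher and 2 lower, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00730, adjusted p = 0.1002 with an estimated correlation, 6 of 100 splits). Igfbp2 rose from 761 ± 68.5 to 1111 ± 54.9 FPKM, and Igf1 and Egfr fell from 67.0 ± 4.38 to 46.5 ± 4.24 FPKM and from 77.9 ± 10.4 to 42.3 ± 12.2 FPKM.

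**Figure D4:**
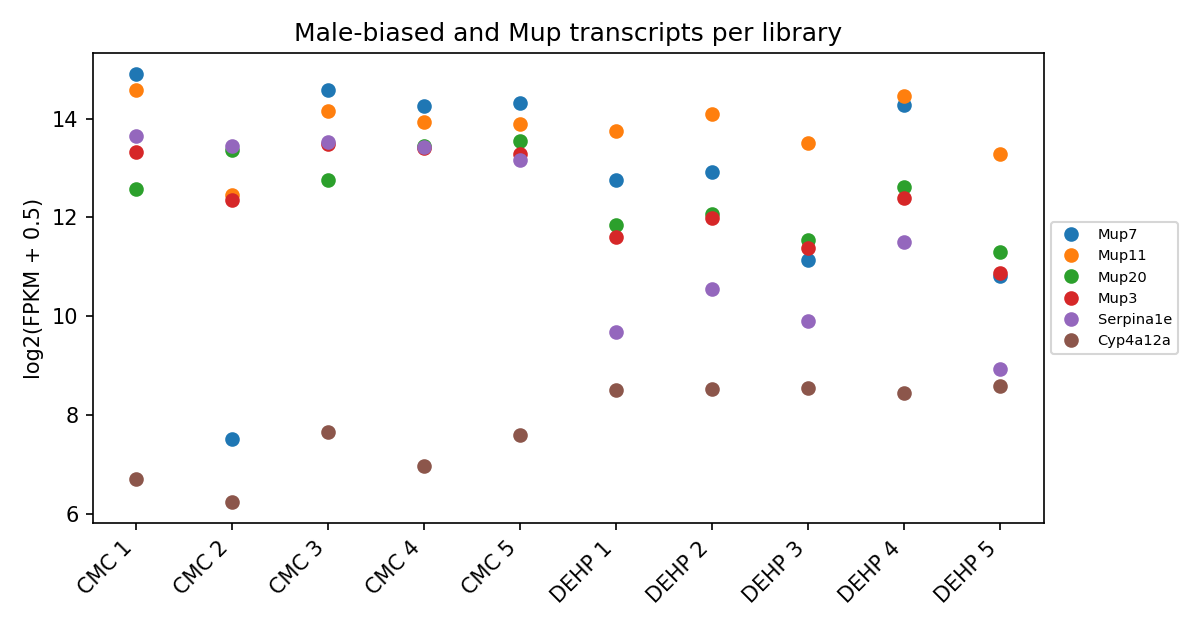
Levels of 6 male-biased or Mup transcripts in each of the 10 libraries as log2(FPKM + 0.5), with 1 colour per gene. Mup7 in CMC library 2 lies at 184 FPKM, far below the other CMC libraries, while Serpina1e in that library lies with the other CMC libraries.

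Of the proteasome genes 21 of 31 were higher and 0 lower, with 28 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.68e-12, adjusted p = 0.115 with an estimated correlation, 1 of 100 splits). Psmb5, a catalytic subunit, rose from 139 ± 10.3 to 213 ± 32.3 FPKM. Of the nuclear-encoded genes of oxidative phosphorylation 14 of 46 were higher and 0 lower, with 24 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.77e-07, adjusted p = 0.440 with an estimated correlation, 13 of 100 splits). Ndufb3, a subunit of the first respiratory complex, rose from 82.1 ± 4.63 to 123 ± 5.48 FPKM. Of the stress response list 6 of 27 were lower and 2 higher, with 2 higher and 11 lower adjusted over the list alone (camera adjusted p = 5.58e-06, adjusted p = 0.115 with an estimated correlation, 9 of 100 splits). Ddit3 and Atf5, transcription factors of that response, fell from 21.3 ± 6.22 to 11.2 ± 0.596 FPKM and from 223 ± 30.0 to 148 ± 15.99 FPKM, and Gdf15 was at -0.24 (SE 0.48, adjusted p = 0.821). Of the cytosolic heat shock list 2 of 13 were higher and 1 lower, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.106, adjusted p = 0.640 with an estimated correlation). Without CMC library 1 its camera adjusted p at the preset correlation was 0.0353. The higher heat shock members, Hspd1 and Hspe1, encode the mitochondrial chaperonin. Of the ribosomal protein genes 1 of 49 was higher, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.458, adjusted p = 0.9425 with an estimated correlation). At the preset correlation its camera adjusted p was 0.00312 without CMC library 2 and 0.0416 without DEHP library 2.

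Few markers of other liver cell types passed the threshold. By limma, 0 of 15 Kupffer cell and macrophage markers passed the threshold, with 3 higher and 0 lower at an unadjusted p below 0.05 (camera adjusted p = 0.282). Limma also passed 0 of 17 sinusoidal endothelial markers, with 1 higher and 0 lower at an unadjusted p below 0.05 (camera adjusted p = 0.551). It passed 0 of 6 B and plasma cell markers, with 2 higher and 1 lower at an unadjusted p below 0.05 (camera adjusted p = 0.448). The exact permutation test per gene gave no adjusted p below 0.0742 for any tested gene, so it holds no information on these lists. Krt23, a keratin, was the 1 higher cholangiocyte marker of 8, rising from 0.784 ± 0.597 to 11.9 ± 2.99 FPKM, while Sox9 was at -0.07 (SE 0.23, adjusted p = 0.904) and Spp1 at -0.10 (SE 0.14, adjusted p = 0.716) (camera adjusted p of the list = 0.728, with 2 higher and 0 lower adjusted over the list alone). Of the stellate cell markers 1 of 14 was lower, with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00549, adjusted p = 0.440 with an estimated correlation, 19 of 100 splits). Of the erythroid markers 2 of 7 were lower, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000640, adjusted p = 0.251 with an estimated correlation, 20 of 100 splits). Alas2, the erythroid enzyme of heme synthesis, fell from 76.6 ± 5.37 to 46.1 ± 6.07 FPKM. Fewer than 5 members could be tested of the neutrophil, T and NK cell, adipocyte, exocrine pancreas, intestinal and skeletal muscle lists, which took no set test. Of the inflammatory cytokines 0 of 13 passed in limma, with 1 higher and 0 lower at an unadjusted p below 0.05 (camera adjusted p = 0.976). Limma passed 0 of 22 fibrosis genes, with 2 higher and 3 lower at an unadjusted p below 0.05 (camera adjusted p = 0.0793), and 0 of 18 circadian clock genes, with 5 higher and 0 lower at an unadjusted p below 0.05 (camera adjusted p = 0.878). Adjusted over the list alone, 0 members of the Kupffer, endothelial, B cell, cytokine, fibrosis and clock lists passed. Without CMC library 4 or 5, or DEHP library 2 or 4, the fibrosis list had a camera adjusted p of 0.0479, 0.0474, 0.0408 and 0.0292. Those values used the preset correlation. Over all libraries the fibrosis list had an adjusted p of 0.625 with an estimated correlation. Of the interferon response genes 3 of 27 were lower and 1 higher, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.618 with an estimated correlation, 40 of 100 splits), and without CMC library 4 or DEHP library 3 the camera adjusted p was 0.0600 and 0.124.

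Camera with a preset correlation passed 25 of the 50 lists tested, 15 upward and 10 downward. Of these, 3 passed with an estimated correlation: mitochondrial fatty acid oxidation, fatty acid uptake and binding, and complement and coagulation. Pathways annotated in the deposited table were also tested, 285 after a filter on their number of tested genes. There, complement and coagulation cascades had 40 of 88 genes lower and fatty acid degradation 33 of 51 higher. With an estimated correlation both had an adjusted p of 0.156 there and did not pass. Over the other drawn splits of the 10 libraries the median number of lists passed was 15, and 8 of 100 splits, the real one included, passed at least 25. Those other splits mix the groups 4 to 1 or 3 to 2 and so keep part of the difference between them, and how much this or the preset correlation adds to the 15 was not tested. The number of passed lists does not set the real grouping apart from other groupings of these libraries. The split counts printed beside each list give how many of 100 splits, the real one included, had as small a camera p for that list. Those counts were 1, the smallest possible, for 9 lists. With Benjamini-Hochberg adjustment over the 50 lists, the share of splits was 0.0556 for these 9 and at least 0.0769 for the others. By the splits no list was thus below 0.05. Among the lists that passed camera, the split counts were at least 25 for the male-biased, interferon and acute phase lists.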

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

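Set beforehand were the count of gene lists over regroupings and the share of calls of at least 2-fold after rescaling. So was the search for a library apart from its group. The regrouping of the gene counts was planned, but its criterion was written after the result was seen. The other tests in this part were chosen only after the result was seen.

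For each gene named in the text, a library counted as apart when its gap to the nearest of the other 4 in its group exceeded 0.71 of the group's range. This held in 18 of 220 groups of 5 (8.2%), where chance gives about 1 in 20, or 5%, for normally distributed values. FPKM was used here without logs, many of the genes were named for their results, and genes of one library are not independent. The 5% is thus only a rough guide. By library the 18 were 7 in CMC library 2, 3 in DEHP library 3, 3 in DEHP library 5, 2 in CMC library 1, 1 in CMC library 3, 1 in CMC library 5 and 1 in DEHP library 4. Alas2 was lowest in CMC library 2 at 67.1 FPKM, and the nearest CMC library had 77.9 FPKM. Cyp2b9 was highest in DEHP library 5 at 63.5 FPKM, and the nearest DEHP library had 23.4 FPKM. Ddit3 was lowest in DEHP library 3 at 10.2 FPKM, and the nearest DEHP library had 11.3 FPKM. Fabp4 was highest in CMC library 2 at 27.4 FPKM, and the nearest CMC library had 13.2 FPKM. Fabp4 was highest in DEHP library 3 at 44.5 FPKM, and the nearest DEHP library had 16.2 FPKM. Gstt2 was highest in CMC library 5 at 69.1 FPKM, and the nearest CMC library had 51.8 FPKM. Hsd17b11 was lowest in DEHP library 4 at 409.8 FPKM, and the nearest DEHP library had 541 FPKM. Hspd1 was lowest in CMC library 1 at 143 FPKM, and the nearest CMC library had 171 FPKM. Hspe1 was lowest in CMC library 1 at 187 FPKM, and the nearest CMC library had 231 FPKM. Ly6d was highest in DEHP library 5 at 32.1 FPKM, and the nearest DEHP library had 7.96 FPKM. Mmd2 was highest in CMC library 2 at 15.4 FPKM, and the nearest CMC library had 4.04 FPKM. Mup3 was lowest in CMC library 2 at 5204 FPKM, and the nearest CMC library had 10003 FPKM. Pdk4 was highest in DEHP library 3 at 4.14 FPKM, and the nearest DEHP library had 1.67 FPKM. Sdr9c7 was lowest in DEHP library 5 at 4.13 FPKM, and the nearest DEHP library had 5.76 FPKM. Slco1a1 was lowest in CMC library 2 at 56.9 FPKM, and the nearest CMC library had 85.8 FPKM. Tff3 was highest in CMC library 2 at 127 FPKM, and the nearest CMC library had 23.3 FPKM. Vnn1 was highest in CMC library 3 at 9.70 FPKM, and the nearest CMC library had 3.88 FPKM. Cbs was highest in CMC library 2 at 344 FPKM, and the nearest CMC library had 253 FPKM.

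Regrouping the 10 libraries gave 126 possible splits into 5 and 5, of which 100 were drawn. For the number of higher genes, 1 of 100 splits, the real one, gave as many (1025, highest other 3), and for the number of lower genes 1 of 100 (270, highest other 3). Chance is thus unlikely for both counts but not excluded, since 1 of 100 is the smallest share these splits can give. The other splits mix the groups and so put part of the difference into the spread within groups, which lowers their counts. For the number of gene lists passed by camera, 8 of 100 splits, the real one included, gave as many (25, highest other 26), so chance is not excluded.

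More genes were higher than lower in DEHP, at 79.2% of calls. With the 10 most abundant genes left out and the rest rescaled the share was 76.2%, which argues against those 10 genes alone as the whole source of the skew. The 10 most abundant genes of each library took 24.7% of summed FPKM in CMC and 23.3% in DEHP libraries (exact permutation p = 0.119). The 50 most abundant took 46.9% and 42.1%, and their removal was not tested, so a wider fall of abundant transcripts stays open. After median-of-ratios scaling the share over all calls was 58.9%, but that scaling centres the typical gene, with a median log2 fold change of 0.0558 before and -0.0107 after, and so evens the balance by construction. Among calls of at least 2-fold after that scaling, 122 higher and 50 lower, the share was 70.9% (95% exact binomial interval 63.5% to 77.6%, over genes that are not independent). Before that scaling it was 76.9%. The scaling moved the median gene by far less than the 2-fold cut-off, so this share could hardly have fallen and does not test an offset. For large changes a rise driven by DEHP stays open as a hypothesis, and for smaller changes it cannot be told apart from an offset.

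CMC library 2 stood apart, with 307 tested genes at least 2-fold from the mean of the other 4 CMC libraries, against 129 to 165 for those 4. By the same measure DEHP library 5 had 219 genes, against 131 to 151 for the other DEHP libraries. The summed Y-linked level of CMC library 2 (Ddx3y, Eif2s3y, Kdm5d and Uty) was 34.5 FPKM, within the 23.5 to 36.03 of the other CMC libraries. Xist reached 0.07 FPKM at most in any library, and both argue against a female mouse. Its mean over the peroxisomal list was 6.47 on the log2 scale, within the 6.38 to 6.53 of the other CMC libraries and below the 7.01 to 7.26 of the DEHP libraries, which argues against a swap with a DEHP library. Its summed Mup level was 29069 FPKM against 80728 to 111290 in the other CMC libraries. Low sums also occurred in DEHP library 5 at 30635 FPKM and DEHP library 3 at 35454 FPKM, against 56806 to 117799 FPKM in the other DEHP libraries. Reads traded among the 21 Mup rows of this sum do not account for the low Mup values of CMC library 2. Reads assigned to other rows or dropped upstream were not checked. A swap with a library outside the series and a mouse that differed in its physiology stay open, and no biological explanation was tested, since the labels name none for this library.

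Pparg mRNA was higher in DEHP although the labels give a liver-specific knockout, with a log2 fold change of 0.89 (SE 0.21, 95% interval 0.45 to 1.33, n = 5 per group). A larger share of macrophages is argued against, since the mean of their 15 tested markers rose by 0.16 (95% interval −0.01 to 0.34). Fat in the samples is argued against by the 5 adipocyte markers under 1 FPKM in CMC, whose sum rose by 0.534 FPKM (95% interval −0.512 to 1.58) against 3.56 for Pparg, but this set was picked after Adipoq alone (at most 0.25 FPKM) and all 9 markers had been tried. Over all 9 markers the sum changed by −157 FPKM (95% interval −535 to 220), and fat cannot be told apart there because Car3, which CMC livers hold at 1106 FPKM, dominates the sum. The mean of Car3 fell to 937 FPKM in DEHP. The means of the other markers above 1 FPKM in CMC were higher in DEHP. Adrb3 went from 4.33 to 8.26 FPKM, Fabp4 from 13.9 to 19.4 FPKM and Lipe from 3.86 to 5.58 FPKM. The argument against fat thus rests on the low markers only. With the circadian component as a covariate the fold change was 0.86 (SE 0.27, 95% interval 0.28 to 1.44) and the call ended because the SE rose, so collection time is argued against as the whole source, and a response to DEHP stays open as an untested hypothesis.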

How the results depend on the processing

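The circadian covariate and the removal of CMC library 2 with DEHP library 5 were tests chosen only after the result was seen, and the other alternatives were planned. For each changed value below the cause was not tested, unless it is given. The counts of 1025 higher and 270 lower genes stayed within 1.5 times under the other pseudocounts, both filters, rescaling without abundant genes, limma without trend and robust variance, array weights and the removal of both libraries (828 to 1149 higher and 220 to 290 lower). Leaving out each library in turn gave 747 to 1011 higher and 202 to 263 lower. Median-of-ratios scaling gave 639 and 445, quantile normalization 611 and 546, and the circadian covariate 540 and 148. A test against a fold of 1.5, which asks for larger changes by construction, gave 57 and 7. The exact permutation test per gene gave 0 and 0, against 1997 and 684 at an unadjusted p below 0.05 and 2086 and 741 in limma. Its smallest p, 0.00794, was shared by 1203 genes, so that 0.0742 was the smallest adjusted p it gave. Pparg, whose log2 fold change of 0.89 that test does not estimate anew, had an adjusted p of 0.110 there, and a log2 fold change of 0.86 with an adjusted p of 0.0813 under the circadian covariate. Of the 110 genes named in the text and tested, 93 were called, and 0 of the called genes changed direction. Among the genes not called, Mup11, Sox9, Spp1 and Gdf15 changed sign under some alternative. Under the circadian covariate 20 of the named genes lost their call. With the replicate number as a block there were 816 higher and 229 lower genes, and the acute phase list lost its call (0.149). No pairing by number was seen, since same-numbered residuals correlated at −0.0722 to 0.0489 and 0 libraries correlated best with their own number. A weak pairing is not excluded by these values. No list changed its call with another pseudocount, array weights, limma without trend and robust variance or rescaling without abundant genes. Camera adjusted p values at the preset correlation changed sides elsewhere as follows. With no filter ketogenesis passed (0.0270) and acute phase did not (0.0591). At 2 FPKM ketogenesis passed (0.0137), and triglyceride synthesis (0.0750) and interferon (0.298) did not. Acute phase did not pass with median-of-ratios scaling (0.0864), nor did triglyceride synthesis, acute phase and interferon with quantile normalization (0.0653, 0.0653 and 0.0590). Under the circadian covariate ketogenesis (0.0233), heat shock (0.00633) and amino acid catabolism (0.0296) passed. Without both libraries heat shock (0.0488), Mup (0.000258) and ribosomal proteins (0.0261) passed. Leaving out each library moved acute phase over 0.00119 to 0.435, heat shock over 0.0353 to 0.281, ribosomal proteins over 0.00312 to 0.987, fibrosis over 0.0292 to 0.299, immediate early genes over 0.0217 to 0.302, interferon over 0.000188 to 0.124, ketogenesis over 0.0293 to 0.140 and Mup over 2.67e-05 to 0.699. With an estimated correlation in place of the preset one these lists no longer passed: peroxisomal 0.0576, omega oxidation 0.1002, thioesterases 0.115, PPAR alpha 0.111, PPAR gamma 0.0576, lipogenesis 0.518, cholesterol synthesis 0.193, triglyceride synthesis 0.159, CAR and PXR 0.160, NRF2 0.518, stress response 0.115, acute phase 0.625, interferon 0.618, male-biased 0.455, female-biased 0.125, growth hormone 0.1002, oxidative phosphorylation 0.440, proteasome 0.115, periportal 0.268, hepatocyte identity 0.0576, stellate 0.440 and erythroid 0.251. Fry, which does not compare a list with other genes, passed ketogenesis (0.00144), lipid droplet proteins (0.000547), thyroid hormone and retinoid metabolism (0.00120) and cholangiocyte markers (0.0307). It did not pass acute phase (0.487), interferon (0.408), male-biased (0.215), periportal (0.0611), stellate (0.248) or erythroid genes (0.0523). Total depth is unknown, so the counting error of low genes has no interval here.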

Other observations

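The gene lists below were fixed beforehand, and the split counts and the tests of annotated pathways were chosen only after the result was seen.

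Genes of thyroid hormone and retinoid handling changed in both directions. Of the thyroid hormone and retinoid list 6 of 24 tested members were higher and 2 lower, with 7 higher and 4 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.405, adjusted p = 0.625 with an estimated correlation, 33 of 100 splits). The retinol dehydrogenase gene Rdh16 rose from 19.0 ± 2.63 to 69.6 ± 16.7 FPKM (SD, n = 5 each) and Aldh1a1, a retinal dehydrogenase, from 552 ± 149 to 1105 ± 65.0 FPKM. Central carbon genes also went both ways. Of the glycolysis and gluconeogenesis list 5 of 28 were higher and 4 lower, with 6 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.425). Pcx, the pyruvate carboxylase, rose from 92.9 ± 6.56 to 122 ± 11.4 FPKM, and Fbp1, a gluconeogenic phosphatase, and Khk, the fructose kinase, fell from 717 ± 104 to 484 ± 31.6 FPKM and from 349 ± 22.8 to 265 ± 18.5 FPKM. In the list of amino acid catabolism and the urea cycle 4 of 41 were higher and 2 lower, with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.636). Bckdha, a subunit of the branched-chain keto acid dehydrogenase, rose from 163 ± 4.51 to 219 ± 17.6 FPKM, and Cbs, which makes cystathionine, fell from 263 ± 45.5 to 171 ± 9.42 FPKM. The nuclear receptor list had 4 of 33 higher and 0 lower, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.922). Its higher members were Pparg, Cebpb, Esrra and Rxrb. Cebpb lost its call without DEHP library 3 or 5 (adjusted p = 0.0506 to 0.0516), Esrra without CMC library 1, 3, 4 or 5, or DEHP library 2, 3 or 4 (adjusted p = 0.0510 to 0.0887) and Rxrb without CMC library 1, 3, 4 or 5, or DEHP library 1, 2, 3 or 5 (adjusted p = 0.0605 to 0.102). With the circadian component as a covariate the adjusted p of Pcx was 0.0774.

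Few growth and damage genes passed the threshold. Of the cell cycle list 2 of 28 were higher and 1 lower, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.766). The replication genes Mcm6 and Cdc45 rose from 1.38 ± 0.713 to 2.89 ± 0.328 FPKM and from 0.518 ± 0.162 to 1.47 ± 0.506 FPKM, and Rrm2, a ribonucleotide reductase subunit, fell from 4.11 ± 0.645 to 2.27 ± 0.402 FPKM. With the circadian covariate Mcm6 and Cdc45 had adjusted p of 0.0866 and 0.0948. Among p53 targets 1 of 17 was higher, Bbc3, at 4.79 to 8.41 FPKM, a call lost without CMC library 1 or 4, or DEHP library 1, 3, 4 or 5 (adjusted p = 0.0570 to 0.0859), with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.976). Of the glucocorticoid-responsive genes 1 of 16 was higher, Ddit4, from 7.61 ± 2.20 to 21.6 ± 10.9 FPKM, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.861). Of the immediate early genes 1 of 14 was lower, Ier2, from 32.1 ± 3.09 to 23.5 ± 2.53 FPKM, with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0939). Under the circadian covariate Ddit4 and Ier2 had adjusted p of 0.0755 and 0.0511. Leaving out CMC library 1, DEHP library 1 or DEHP library 5 brought the camera adjusted p of the immediate early genes to 0.0217, 0.0473 and 0.0367. Those values used the preset correlation. Over all libraries the immediate early genes had an adjusted p of 0.518 with an estimated correlation. Among the short lists that took no set test, the intestinal markers Fabp2, Apoa4 and Lgals4, which CMC livers also held, had log2 fold changes of 0.93, -1.81 and -1.16, all past the threshold. The pancreatic marker Cela1 fell from 65.0 ± 20.8 to 33.1 ± 5.64 FPKM, a call lost without CMC library 1, 3, 4 or 5, or DEHP library 1, 2, 3, 4 or 5 (adjusted p = 0.0526 to 0.107). Under the circadian covariate Lgals4 had an adjusted p of 0.0664. By limma 0 of 3 neutrophil, 0 of 4 T and NK cell, 0 of 4 adipocyte and 0 of 1 skeletal muscle markers passed, with 0, 1, 2 and 0 at an unadjusted p below 0.05.

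From the pathways annotated in the deposited table, 285 were kept by a filter on their number of tested genes. Camera with the preset correlation passed 39 of these. With an estimated correlation 0 passed, and the smallest adjusted p was 0.156. Of 55 genes of valine, leucine and isoleucine degradation 29 were higher and 2 lower (camera adjusted p = 2.29e-11, adjusted p = 0.156 with an estimated correlation), and of 31 genes of the citrate cycle 14 were higher and 0 lower (camera adjusted p = 1.60e-06, adjusted p = 0.303 with an estimated correlation). Of 28 genes of butanoate metabolism 16 were higher and 0 lower (camera adjusted p = 3.17e-09, adjusted p = 0.156 with an estimated correlation). The preset correlation also passed many gene lists when the libraries were regrouped, so the number of passed pathways is given without a claim about its size.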
